A study of Mus musculus with 14 samples.

How the data were processed

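Gene expression was measured in neocortical progenitors of CD1 mouse embryos that had received an expression vector by in utero electroporation, in which DNA is injected into the ventricle of the embryonic brain and driven into the lining cells by electric pulses. Per the labels, the injection was made at E14.5, the vector carried either Fezf2 with GFP (Fezf2GFP) or GFP without it (CtrlGFP), and GFP-positive cells were purified by FACS at 24 h or 48 h. The 14 arrays form 4 groups: CtrlGFP at 24 h (n = 3), Fezf2GFP at 24 h (n = 3), CtrlGFP at 48 h (n = 4) and Fezf2GFP at 48 h (n = 4). Nothing in the labels says that the arrays of a group came from separate litters, so p-values measure the spread between these samples, part of which may be technical. Per the labels' protocols, RNA was amplified by 2 rounds of in vitro transcription before hybridization to Affymetrix mouse arrays.

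The deposited values are on the log2 scale, and the authors' software is named as GCRMA in the submitters' processing notes; its version and settings are not given in the sources used here. No scanner files were used here, so background correction, normalization between arrays and the summary over probes are those of the authors. The value table holds 45037 probe sets, with values from 0.43 to 16.47 and array medians from 3.26 to 3.50. Signal over background limits the dim genes, and the number of arrays limits the precision of every comparison. Of the probe sets, 34945 were paired with 1 gene symbol in the platform annotation used here, 932 with several and 9160 with none. Symbols were checked through the Entrez gene ID against a table of RefSeq genes of assembly GRCm38.p6, and 0 of them changed. That table was otherwise used only for the span of each gene, found for 99.9% of the genes tested, and no coordinates are reported, since the build behind the array annotation is not given in the sources used here.

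For each of 18193 symbols the probe set with the highest mean over the 14 arrays was taken, from those paired with exactly 1 symbol. A gene was tested if this probe set lay above the dim level of 4 in at least 3 of the 14 arrays, which left 10295 genes and set aside 7898. A linear model with a mean per group was fitted to all 14 arrays with limma 3.58.1 (lmFit and eBayes, default prior) in R 4.3.3, which left 10 residual degrees of freedom. The 5 comparisons were Fezf2GFP against CtrlGFP at 24 h and at 48 h, the difference between these 2 effects (the interaction), and 48 h against 24 h with each vector. Adjusted p-values are Benjamini-Hochberg values from limma over the genes tested, with a threshold of 0.05, and "passed" refers to that threshold. Errors beside a fold change are limma's standard errors (SE); those beside a level are standard deviations (SD). Where every array of a group lay below the dim level, the fold is a lower bound against the higher of that level and each array's own value, and is written "at least".

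Before the data were examined, 24 gene lists were fixed, covering cortical cell types, signalling pathways, stress responses and other cell types that the sorting gate could hold. Lists with at least 5 tested members (20 of the 24) were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera sets a list against the other genes tested, so a list it calls higher or lower is so relative to them. The median log2 fold change of all genes tested was 0.056 for Fezf2GFP at 24 h and 0.063 at 48 h. Camera with an estimated correlation and limma's fry, whose directional p asks whether the genes of a list move on balance one way, were alternatives. The camera tests of the comparisons between times were added after the data were seen. The rule for naming genes was also fixed before the data were examined. It takes 11 genes fixed by name, the 8 largest rises and 8 largest falls that passed without overlap between the arrays of each Fezf2GFP comparison, up to 3 passing members of each tested list by p (or 2 that did not pass where none passed), the 8 smallest p of the interaction, and the 5 largest rises and falls that passed in each comparison between times. Of the 11 genes fixed by name, 9 were tested, 1 lay below the dim level and 1 was not analysed here.

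The functions were tested on simulated data with the real gene means and spreads, in which 200 of 10295 genes were changed. For 24 h, 89.0% of genes changed by a log2 fold change of 2 and 30.0% of those changed by 1 were recovered, with 5 false calls among 124. For 48 h the shares were 93.0% and 55.0%, with 3 false calls among 151. A simulated shift of 0.8 in the 11 tested corticothalamic genes was called at both times, with 0 other lists called. The simulated noise was independent between genes, so these counts do not measure false calls where genes vary together.

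Alternatives were no filter on dim probe sets, a dim level of 6, quantile normalization or median centring of the deposited values, all probe sets tested singly, the mean of a gene's probe sets, eBayes with trend and robust, array weights, only the groups compared, the replicate number as a block, and each array left out in turn. Further alternatives were added after seeing the data: leaving out the 2 control arrays that stood apart (24 h replicate 1 and 48 h replicate 2), leaving out these and Fezf2GFP 48 h replicate 1, and removing from each array its lowess trend with log2 gene span. Fezf2 had 1 probe set, which left the planned comparison of its probe sets without a value.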

Results

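Transcripts of GFP-positive cells sorted from the cortex of mouse embryos were measured on 14 arrays, 3 per vector at 24 h and 4 per vector at 48 h after electroporation at E14.5. At that stage cortical progenitors mainly produce upper-layer neurons. The series asks what forced expression of Fezf2, a transcription factor of corticospinal and other deep-layer projection neurons, changes in them by 48 h. Arrays of a group correlated at 0.942 to 0.993 across the tested genes. Array medians lay between 3.26 and 3.50 on the log2 scale. The 2 highest medians were those of CtrlGFP 24 h replicate 1 and CtrlGFP 48 h replicate 2, whose deviations from their group means correlated at 0.593 with each other across genes.

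Fezf2 itself was measured by 1 probe set, and its level went against the label. At 24 h Fezf2 stood at 11.30 ± 0.42 (SD, n = 3) in the arrays labelled CtrlGFP and at 9.44 ± 0.11 (SD, n = 3) in those labelled Fezf2GFP. All Fezf2GFP arrays lay below all control arrays, and the log2 fold change was -1.86 (SE 0.38, limma adjusted p = 0.0324). At 48 h the levels of Fezf2 were 10.15 ± 0.48 and 9.33 ± 0.70 (SD, n = 4 each), a difference that did not pass (log2 fold change -0.82, SE 0.33, limma adjusted p = 0.239). Whether this probe set lies in the part of the transcript that the vector carries is not given in the sources used here. It therefore does not check the labels, and every direction given here for Fezf2GFP against CtrlGFP rests on the labels alone. The fall of Fezf2 at 24 h passed in 18 of 27 alternative fits. Leaving out CtrlGFP 24 h replicate 2 (adjusted p = 0.141) or replicate 3 (0.121), or Fezf2GFP 24 h replicate 1 (0.157), replicate 2 (0.0933) or replicate 3 (0.0929), ended the call. In these fits the log2 fold change of Fezf2 lay between -1.89 and -1.74.

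Among the other genes fixed by name, Ephb1, an ephrin receptor used in axon guidance, rose in the arrays labelled Fezf2GFP at 48 h. Its log2 fold change was 1.62 (SE 0.35, limma adjusted p = 0.0256, n = 4 against 4), with no overlap between the vectors. The 24 h value of Ephb1, 0.50 (SE 0.41, adjusted p = 0.726), did not pass. Bcl11b, a transcription factor of subcerebral projection neurons, had log2 fold changes of 1.08 at 24 h (SE 0.34, adjusted p = 0.215) and 0.97 at 48 h (SE 0.29, adjusted p = 0.0986). All 3 other Bcl11b probe sets had the same sign at both times. Crym, a marker of corticospinal neurons, stood at 2.08 (adjusted p = 0.476, with 2 of 3 control arrays below the dim level) and 2.88 (adjusted p = 0.057, with 1 of 4 below it). Cux2, a transcription factor of upper layers, stood at -0.29 (adjusted p = 0.779) and -0.98 (adjusted p = 0.0769). None of these 3 passed at either time, and neither did Tbr1 (0.39 and 0.78), Eomes (0.15 and 0.52), Pax6 (0.18 and 0.17) or Gad1 (2.22 and 0.79). Slc17a7 lay between 2.83 and 3.11 on all 14 arrays, below the dim level of 4, and was not tested. The call of Ephb1 held in 18 of 27 alternative fits, over which its log2 fold change ranged from 1.31 to 1.86 and its adjusted p from 0.00561 to 0.0804. This call ended with the trend with gene span removed (log2 fold change 1.31, limma adjusted p = 0.0772). It also ended without CtrlGFP 48 h replicate 2 (0.0627), replicate 3 (0.0731) or replicate 4 (0.0804), and without Fezf2GFP 48 h replicate 2 (0.0663), replicate 3 (0.0637) or replicate 4 (0.0633).

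**Figure D1:**
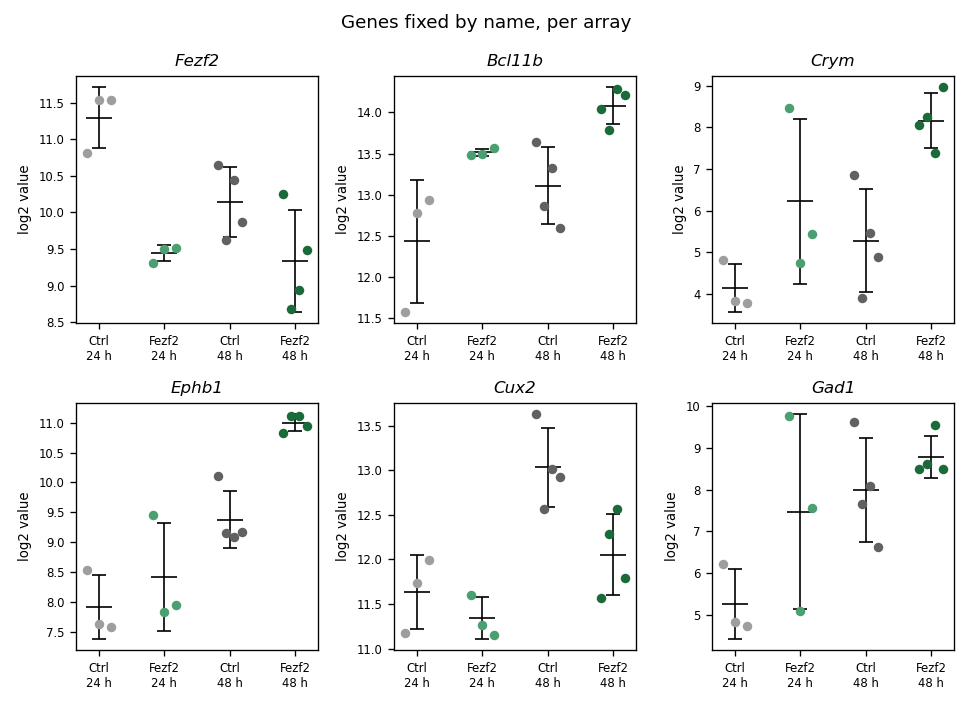
Log2 value (vertical axis) of 6 of the genes fixed by name on each of the 14 arrays (points), by labelled vector and time, with the group mean and SD (bars; n = 3 at 24 h and 4 at 48 h). The 3 arrays labelled Fezf2GFP at 24 h lie below all 3 control arrays for Fezf2, and Ephb1 is higher in all 4 Fezf2GFP arrays at 48 h than in all 4 control arrays.

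At 24 h the largest changes in the arrays labelled Fezf2GFP were rises, several of them of genes near or below the dim level in the controls. Slc26a7, an anion exchanger, rose from 3.68 ± 0.71 to 10.16 ± 0.39 (SD, n = 3 each), a log2 fold change of 6.48 (SE 0.73, limma adjusted p = 0.000771). In 1 of the 3 control arrays it lay above the dim level. Uncx, a homeobox transcription factor, rose at least 13.4-fold (adjusted p = 0.00169). Hpgd, an enzyme of prostaglandin breakdown, rose at least 12.6-fold (adjusted p = 0.00959), and Frem1, an extracellular matrix protein, at least 10.6-fold (adjusted p = 0.00104). Slc4a10, a bicarbonate transporter, had a log2 fold change of 4.02 (SE 0.72) and Cpxm2 of 3.98 (SE 0.32). Wls, which carries Wnt proteins to the cell surface, rose by 3.94 (SE 0.62, with 2 of 3 control arrays below the dim level) and Cyp7b1, an oxysterol hydroxylase, by 3.63 (SE 0.63). Over the alternative fits the log2 fold changes of Slc26a7, Cpxm2, Wls and Cyp7b1 went as low as 3.23, 2.03, 2.10 and 2.11. That of Hpgd went as low as 2.32, under its bound, so the bound holds for the main fit only.

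The largest falls at 24 h were in Rai2 (-2.78, SE 0.31, limma adjusted p = 0.000761), Srebf1, a transcription factor of lipid synthesis (-2.70, SE 0.28), and Zfhx4, a zinc finger homeobox factor (-2.34, SE 0.42). Next came Btbd17 (-2.25, SE 0.23), Klhl35 (-1.97, SE 0.35, with 2 of 3 Fezf2GFP arrays below the dim level), 2210408K08Rik (-1.88, SE 0.19), Fezf2 and Adcyap1r1, a neuropeptide receptor (-1.79, SE 0.27). Over the alternative fits the falls of Btbd17 and Adcyap1r1 were as small as -1.17 and -0.62. Klhl35 passed in 21 and Zfhx4 in 19 of 27 such fits. In all, 109 of 10295 genes passed, 83 higher and 26 lower in the arrays labelled Fezf2GFP. For all 109 the 3 arrays of each vector did not overlap, as for 19.6% of all genes tested, against 10% by chance. The count was 50 without CtrlGFP 24 h replicate 2, 66 without CtrlGFP 24 h replicate 3, 55 without Fezf2GFP 24 h replicate 1, 165 without CtrlGFP 48 h replicate 2, 63 with only the groups compared and 2030 with array weights. Fold changes rose with gene span (Spearman's rho = 0.269 across genes, which are not independent replicates), and without the 2 control arrays that stood apart 92 genes passed, 57 higher and 35 lower.

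Of the fixed lists, camera called 7 at 24 h. Glutamate transmission was higher in the arrays labelled Fezf2GFP, with a median log2 fold change of 0.56 (adjusted p = 0.00425, and adjusted p = 0.488 with an estimated correlation). Of its 14 members 1 passed (4 higher adjusted over the list alone), the AMPA receptor subunit Gria1, which rose by 2.38 (SE 0.52, adjusted p = 0.0498, with 1 of 3 control arrays below the dim level). Corticothalamic and deep-layer neurons were higher with a median of 0.72 (adjusted p = 0.00452, and adjusted p = 0.488 with an estimated correlation). Of their 11 members 0 passed (4 higher adjusted over the list alone); Foxp2, a transcription factor of deep layers, stood at 1.17 (SE 0.34) and Nr4a2 at 0.93 (SE 0.28). GABAergic and subpallial neurons had a median of 1.04 (adjusted p = 0.0177, and adjusted p = 0.488 with an estimated correlation). Of their 12 members 0 passed, also 0 adjusted over the list alone, with Dlx5 at 0.93 (adjusted p = 0.295, with 2 of 3 control arrays below the dim level). Lhx6, below the dim level on all control arrays, stood at least 1.60-fold higher and did not pass (adjusted p = 0.505). Immediate early and heat shock genes had a median of 0.49 (adjusted p = 0.0184, and adjusted p = 0.488 with an estimated correlation). Of these 10 genes 0 passed (2 higher adjusted over the list alone), with Fos at 1.15 (SE 0.36) and Hspa1b at 1.00 (SE 0.30).

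Other axon guidance and adhesion genes were higher at 24 h with a median of 0.21 (adjusted p = 0.0297, and adjusted p = 0.488 with an estimated correlation). Of 25 members 2 rose (4 adjusted over the list alone), Robo1, a receptor for Slit proteins, by 2.06 (SE 0.27, adjusted p = 0.0026) and Draxin, a secreted repellent of axons, by 1.10 (SE 0.21, adjusted p = 0.0211). Over the alternative fits these rises went as low as 0.70 and 0.54, and passed in 26 and 19 of 27. Cell division was lower relative to the other genes, with a median of -0.12 (adjusted p = 0.0184, and adjusted p = 0.499 with an estimated correlation). Of its 26 members 0 passed, also 0 adjusted over the list alone, with Cenpe at -0.56 (SE 0.30) and Mcm4 at -0.29 (SE 0.15). Intermediate progenitors were lower relative to the other genes, with a median of -0.12 (adjusted p = 0.0197, and adjusted p = 0.488 with an estimated correlation). Of their 15 members 0 passed (2 lower adjusted over the list alone), with Gadd45g at -1.20 (adjusted p = 0.0774) and Dll3 at -0.89 (adjusted p = 0.145). Camera called 3 lists without CtrlGFP 24 h replicate 3 and 4 without Fezf2GFP 24 h replicate 1, and fry called 4. In these 3 cases, and with no filter on dim probe sets (10 lists higher) or quantile normalization (5 higher), 0 lists were called lower, so both lower calls were lost.

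Outside the lists that camera called at 24 h, Efna3, an ephrin ligand, rose by 1.80 (SE 0.24, limma adjusted p = 0.0026). It was 1 of 14 ephrins and receptors to pass, with 2 higher adjusted over the list alone. That list had a median of 0.21 and was called by fry (adjusted p = 0.0215) but not by camera (adjusted p = 0.298). Cntn6, a neural adhesion molecule, rose by 1.68 (SE 0.36, adjusted p = 0.044) as 1 of 14 corticospinal genes (2 higher adjusted over the list alone; median 0.59, camera adjusted p = 0.0589). Dusp6, a phosphatase induced by FGF signalling, rose by 2.04 (SE 0.44, adjusted p = 0.048) as 1 of 8 FGF targets, also 1 adjusted over the list alone. Axin2, a target of Wnt signalling, fell by 0.83 on the log2 scale (SE 0.18, adjusted p = 0.0468) as 1 of 5 Wnt targets, with 1 higher and 1 lower adjusted over the list alone. Dusp6, Gria1, Cntn6 and Axin2 passed in only 9, 8, 8 and 6 of 27 alternative fits.

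At 48 h Parm1, a mucin-like membrane protein, rose from 5.57 ± 0.50 to 10.66 ± 0.10 (SD, n = 4 each) in the arrays labelled Fezf2GFP, a log2 fold change of 5.09 (SE 0.32, limma adjusted p = 7.45e-06). Rgs8, a regulator of G protein signalling, rose by 4.74 (SE 0.33, adjusted p = 7.62e-06), Slc26a7 by 4.67 (SE 0.64, with 2 of 4 control arrays below the dim level) and Nrp2, a semaphorin receptor, by 4.07 (SE 0.48). Elovl7, a fatty acid elongase, rose by 4.04 (SE 0.41, with 2 of 4 control arrays below the dim level), Shisa6, an AMPA receptor partner, by 3.98 (SE 0.39, with 1 of 4 below it) and Sulf2, a heparan sulfate sulfatase, by 3.52 (SE 0.43). Over the alternative fits the rises of Slc26a7, Elovl7, Shisa6 and Sulf2 went as low as 2.33, 2.39, 1.98 and 1.96, and each passed in 27 of 27. Calb2, which encodes calretinin, was below the dim level on all 4 control arrays and rose at least 10.8-fold (adjusted p = 0.000332). The largest falls were in Flrt3, a membrane protein of adhesion and axon guidance (-3.11, SE 0.36, adjusted p = 0.000459), Zfhx4 (-2.73, SE 0.37), Rai2 (-2.40, SE 0.27) and Klhl35 (-2.39, SE 0.31). Among genes without overlap between the vectors, they were followed by Pdzrn4 (-2.22, SE 0.35), B2m, the light chain of class I histocompatibility molecules (-2.08, SE 0.41), Pdzrn3 (-2.06, SE 0.34) and Srebf1 (-1.72, SE 0.25).

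At this time 322 of 10295 genes passed, 278 higher and 44 lower. For 306 of them the arrays of the vectors did not overlap, as for 9.07% of all genes tested, against 2.86% by chance. The count was 188 without CtrlGFP 48 h replicate 4, 200 without Fezf2GFP 48 h replicate 4, 168 with only the groups compared and 550 with array weights. Fold changes again rose with gene span (rho = 0.281 across genes), and with that trend removed 257 genes passed, 180 higher and 77 lower.

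**Figure D2:**
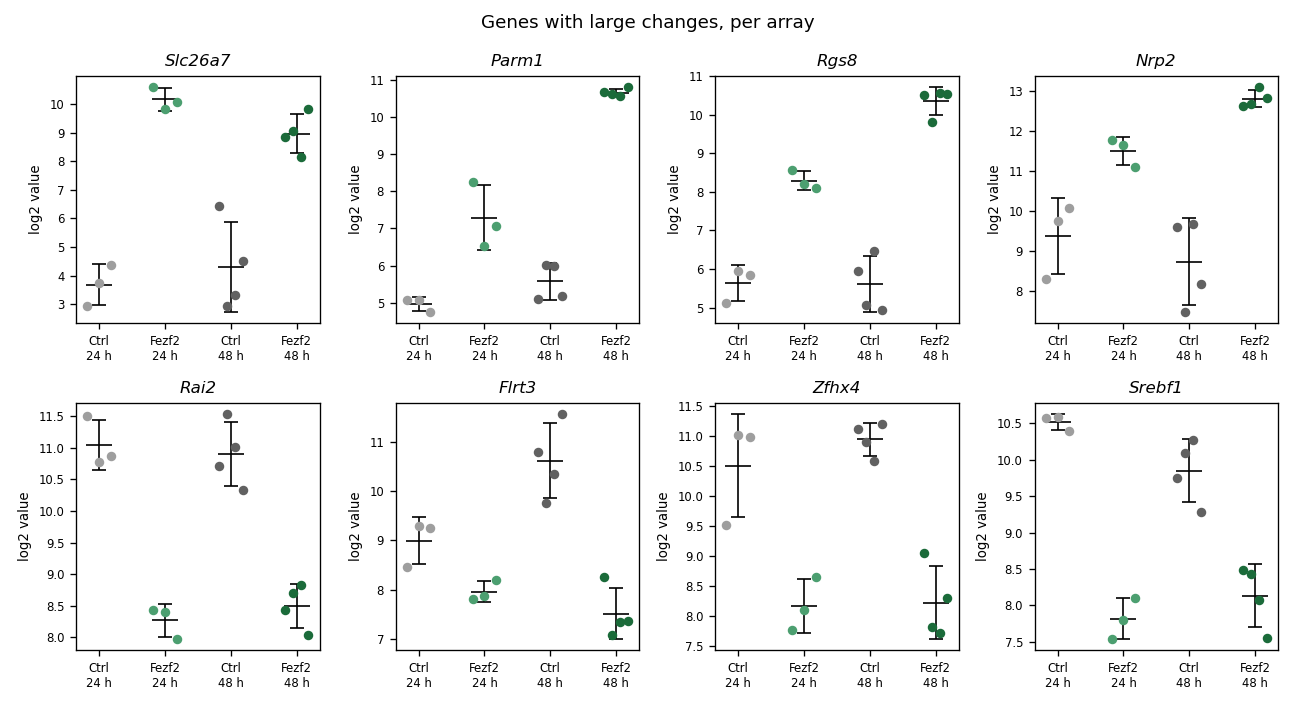
Log2 value (vertical axis) of 8 genes with large changes on each of the 14 arrays (points), by labelled vector and time, with the group mean and SD (bars; n = 3 at 24 h and 4 at 48 h). Parm1 averages 5.57 in the 4 control arrays and 10.66 in the 4 Fezf2GFP arrays at 48 h, and Rai2 is lower in every Fezf2GFP array of each time than in every control array of that time.

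Camera called 8 lists at 48 h. Corticothalamic and deep-layer neurons were higher with a median of 0.78 (adjusted p = 6.11e-05, and adjusted p = 0.483 with an estimated correlation). Of 11 members 1 passed (6 higher adjusted over the list alone), the Wnt ligand Wnt7b, which rose by 2.04 (SE 0.23, adjusted p = 0.000332). Radial glia were higher with a median of 0.53 (adjusted p = 0.00621, and adjusted p = 0.483 with an estimated correlation). Of 20 members 3 rose and 1 fell (10 and 1 adjusted over the list alone). The rises were in the filament gene Nes (1.30, SE 0.21), Ddah1 (0.80, SE 0.20) and Aldoc (0.74, SE 0.18), and the fall in Hopx (-2.28, SE 0.57, adjusted p = 0.0482), chosen after its values were seen. Corticospinal and subcerebral neurons were higher with a median of 0.54 (adjusted p = 0.020, and adjusted p = 0.527 with an estimated correlation). Of 14 members 1 passed, Cntn6 at 1.46 (SE 0.31), and 6 were higher adjusted over the list alone. Glutamate transmission was higher with a median of 0.48 (adjusted p = 0.00991, and adjusted p = 0.483 with an estimated correlation). Of 14 members 0 passed (3 higher adjusted over the list alone), with Grik5 at 1.56 (adjusted p = 0.0542, with 2 of 4 control arrays below the dim level) and Gria3 at 0.89 (adjusted p = 0.0728).

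Ephrins and their receptors were higher at 48 h with a median of 0.30 (adjusted p = 0.0462, and adjusted p = 0.483 with an estimated correlation). Of 14 members 3 rose (5 adjusted over the list alone), Ephb1, Efnb3 by 1.09 (SE 0.25) and Efna3 by 0.91 (SE 0.21). Other axon guidance and adhesion genes had a median of 0.27 (adjusted p = 0.020, and adjusted p = 0.483 with an estimated correlation). Of 25 members 4 rose (8 adjusted over the list alone), Nrp2, Draxin by 1.21 (SE 0.18), Unc5b, a netrin receptor, by 0.81 (SE 0.15) and Robo1 by 1.03 (SE 0.24), the last chosen after its values were seen. Cell division was lower relative to the other genes, with a median of -0.14 (adjusted p = 0.00991, and adjusted p = 0.706 with an estimated correlation). Of 26 members 0 passed, also 0 adjusted over the list alone, with Cdc20 at -0.44 (SE 0.21) and Rrm2 at -0.35 (SE 0.20). Intermediate progenitors were lower relative to the other genes, with a median of -0.07 (adjusted p = 0.020, and adjusted p = 0.483 with an estimated correlation). Gadd45g, a growth arrest gene, fell by 1.57 on the log2 scale (SE 0.25, adjusted p = 0.00441) as the 1 member of 15 that passed, with 1 higher and 2 lower adjusted over the list alone. Fold changes were below 0 for 12 members and above 0 for 3, among them Eomes at 0.52 (limma adjusted p = 0.0949). Camera called 2 lists without CtrlGFP 48 h replicate 3, 2 without Fezf2GFP 48 h replicate 3, 5 without Fezf2GFP 48 h replicate 2 and 3 with the trend with gene span removed, and fry called 5. Of the lists called, 0 were lower by fry, with no filter on dim probe sets (7 higher), or without CtrlGFP 48 h replicate 3 or Fezf2GFP 48 h replicate 3. Ddah1, Aldoc, Efnb3 and Efna3 passed at 48 h in only 10, 12, 15 and 17 of 27 alternative fits, Ddah1 with an adjusted p of 0.260 with the trend with gene span removed.

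Callosal and upper-layer genes were not called at 48 h (median 0.08, mean 0.15, camera downward with adjusted p = 0.926). Of 23 members 2 rose, the activin subunit Inhba by 1.59 (SE 0.28) and Dkk3 by 1.71 (SE 0.35), with 4 higher and 2 lower adjusted over the list alone. At 24 h the same list had a median of 0.25 (adjusted p = 0.737), and 0 of 23 members passed (1 higher adjusted over the list alone), with Chn2 at 1.80 (adjusted p = 0.0921) and Gucy1a1 at 2.22 (adjusted p = 0.314). Among oligodendrocyte and astrocyte genes at 48 h (median 1.01, mean 0.22, adjusted p = 0.412), 2 of 5 rose, Aldh1l1 by 1.41 (SE 0.23) and Mbp by 1.01 (SE 0.21), with 3 higher and 2 lower adjusted over the list alone.

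**Figure D3:**
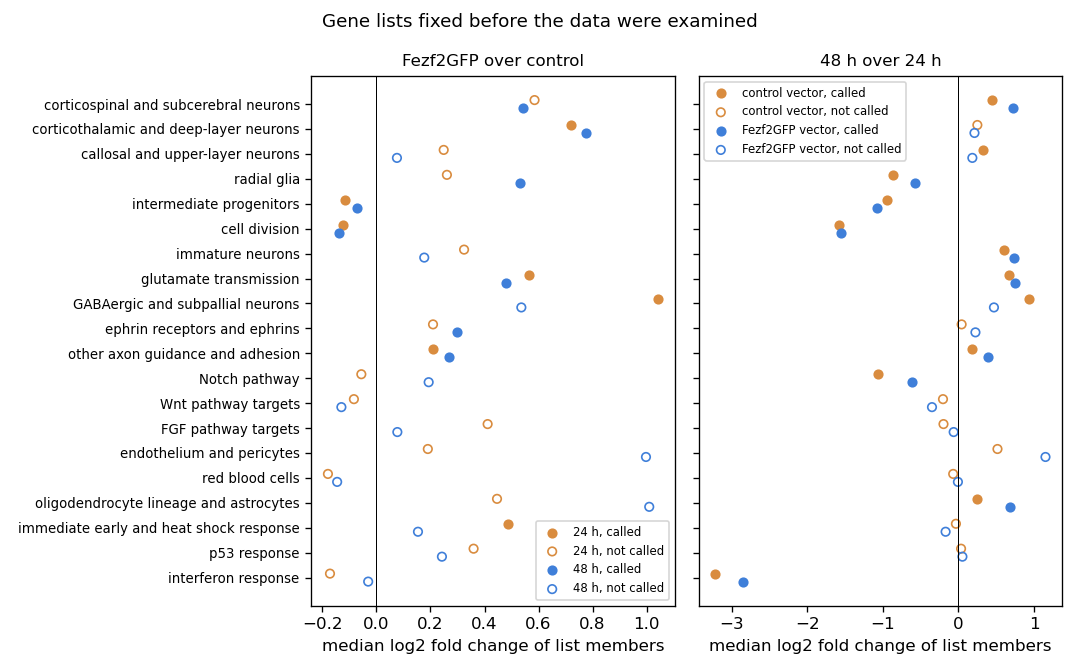
Median log2 fold change of the tested members (horizontal axis) of the 20 lists tested, for labelled Fezf2GFP over control at 24 h and 48 h (left panel) and for 48 h over 24 h with each vector (right panel; the 2 panels have different scales); filled points passed camera with the preset correlation. The medians for Fezf2GFP lie between -0.18 and 1.04, and the interferon list reaches -3.22 between times in controls.

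The effects at the 2 times, which share no arrays, had a Pearson's r of 0.54 and a Spearman's rho of 0.49 across genes, which are not independent replicates. In the main fit Slc26a7, Robo1, Draxin, Efna3 and Cntn6 rose and Rai2, Srebf1, Zfhx4 and Klhl35 fell at both 24 h and 48 h. Over 27 alternative fits Cntn6 passed in only 8 at 24 h, Draxin and Zfhx4 in 19 and Klhl35 in 21. At 48 h Efna3 passed in 17 and Cntn6 in 20. Of the genes called, 42 were higher at both times, against 2.24 for independent lists, 9 were lower at both, against 0.111, and 0 were called in opposite directions. Both comparisons use the same estimate of each gene's spread, so a gene of low spread is likelier to be called in both. The values for independent lists are therefore not what chance gives. Of the 109 genes called at 24 h, 102 had the same sign at 48 h. The correlation was 0.34 without CtrlGFP 48 h replicate 2, 0.44 without Fezf2GFP 48 h replicate 4 and 0.41 without both control arrays that stood apart. Of 100 regroupings of the arrays, 3 gave as high a correlation with all arrays, 10 without CtrlGFP 48 h replicate 2 and 12 without Fezf2GFP 48 h replicate 4, so chance is not excluded.

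**Figure D4:**
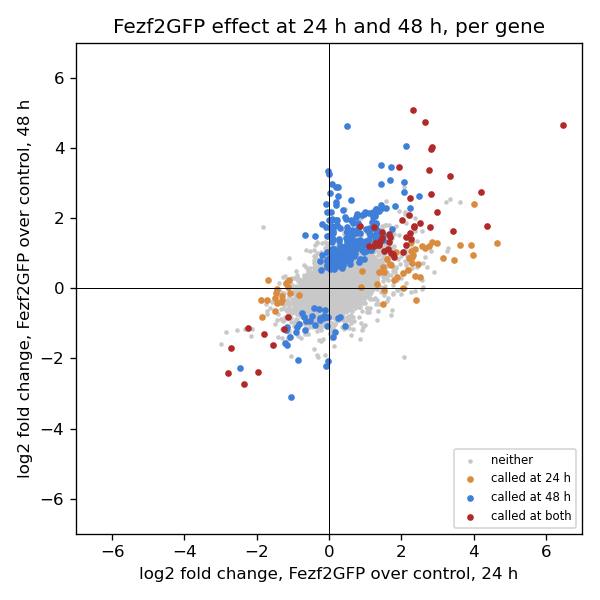
Log2 fold change of labelled Fezf2GFP over control at 24 h (horizontal axis) against that at 48 h (vertical axis) for the 10295 genes tested (points), coloured by the times at which limma's adjusted p passed. Slc26a7 lies farthest right, at 6.48 and 4.67, and 42 genes are higher and 9 lower at both times.

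Col9a1, a collagen chain, was higher in the arrays labelled Fezf2GFP at 24 h (9.02 against 6.62) and not at 48 h (7.68 against 8.02), with a difference of effects of -2.73 (SE 0.39, limma adjusted p = 0.0159). Hmgcll1 had a difference of 1.95 (SE 0.30) and Pappa2, a protease of insulin-like growth factor binding proteins, of 1.88 (SE 0.26), with all group means above the dim level. Outside Fezf2GFP at 48 h (6.61 and 6.75) their means lay near that level, at 4.45 to 4.65 and 4.66 to 4.80. Cpxm2 was higher in Fezf2GFP at 24 h (8.05 ± 0.68 against 4.08 ± 0.23, SD, n = 3) and at least 1.35-fold higher at 48 h, where its controls lay below the dim level (interaction adjusted p = 0.0159). For 4 further genes 3 groups lay below the dim level on every array, so the size of the difference is not measured and only a bound at 1 time is given. Tmem117 (at least 4.46-fold), Cdhr1, a cadherin-related protein (at least 2.27-fold), and Stac2 (at least 1.96-fold) were higher in Fezf2GFP at 48 h, and Trim5 (at least 2.01-fold) at 24 h. By limma's test of the interaction the effect of the vector differed between the times for 10 genes, 7 with a higher effect at 48 h and 3 with a lower one. An unadjusted p below 0.05 was found for 509 of 10295 genes, about the share of 0.05 that chance alone gives. Of the 20 lists tested, camera called 0 for this difference. The count of genes was 0 without CtrlGFP 24 h replicate 2 (392 unadjusted), CtrlGFP 24 h replicate 3 (659), CtrlGFP 48 h replicate 3 (474) or Fezf2GFP 24 h replicate 3 (363), and 3 without CtrlGFP 24 h replicate 1. It was 4 without Fezf2GFP 24 h replicate 1 or replicate 2, 5 without CtrlGFP 48 h replicate 4, 4 with a dim level of 6 and 240 with array weights. With the replicate number as a block 0 genes passed.

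Between 24 h and 48 h, interferon-induced genes fell with both vectors. In control cells Bst2, an antiviral membrane protein, went from 9.09 ± 1.21 (SD, n = 3) to 3.18 ± 0.77 (SD, n = 4), a fitted log2 fold change of -5.91 (SE 0.55, limma adjusted p = 5.17e-05). At 48 h 3 of these 4 arrays lay below the dim level, so the size of the fall is not measured. Rtp4 fell at least 24.9-fold by the probe set taken, with fitted log2 fold changes of -5.28 to -2.94 over the alternative fits. The other largest falls were Ifi35 (-4.95, SE 1.35), Usp18 (-4.85, SE 0.85) and Oasl2 (-4.81, SE 0.58). The largest fitted rises in controls were Tafa2 (5.21, SE 0.56), Lonrf2 (4.99, SE 0.75), Dlg2, a postsynaptic scaffold protein (4.97, SE 0.46), Btbd11 (4.73, SE 0.63) and Jakmip1 (4.57, SE 0.58). Their lowest values over the alternative fits were, in this order, 5.1, 2.6, 2.0, 3.6 and 2.0. Lonrf2 and Dlg2 lay below the dim level on 2 of 3 control arrays at 24 h, and Ifi35 and Oasl2 on 2 of 4 at 48 h, so their sizes and order are uncertain. In the arrays labelled Fezf2GFP, Bst2 fell at least 23.8-fold. Usp18 (-5.21, SE 0.85), Gbp3, an interferon-induced GTPase (-5.07, SE 0.59), Ifi35 (-5.00, SE 1.35) and Oasl2 (-4.93, SE 0.58) fell as well. The largest fitted rises there were Lypd6b (4.76, SE 0.37), Calb2 (at least 10.8-fold), Abcc8, a subunit of potassium channels (3.88, SE 0.27), the GABA receptor subunit gene Gabra2 (3.81, SE 0.55) and B4galnt1, an enzyme of ganglioside synthesis (3.70, SE 0.42). Lypd6b and B4galnt1 lay below the dim level on 2 of 3 Fezf2GFP arrays at 24 h, and at 48 h Ifi35 and Oasl2 did on 3 of 4 and Usp18 and Gbp3 on 1 of 4, so here too sizes and order are uncertain. Ifi35 passed in only 20 of 27 alternative fits in controls and 19 in Fezf2GFP.

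In controls 1294 genes passed between times, 605 higher and 689 lower at 48 h. In the arrays labelled Fezf2GFP 1241 passed, 657 higher and 584 lower. The 2 time effects share no arrays and had a Pearson's r of 0.77 and a Spearman's rho of 0.67 across genes. With both vectors 356 genes were higher and 401 lower at 48 h, against 38.6 and 39.1 for independent lists, and 1 was called in opposite directions. These comparisons too use the same estimate of each gene's spread, so 38.6 and 39.1 are not what chance gives. The count for Fezf2GFP was 670 without Fezf2GFP 24 h replicate 2 and 643 without Fezf2GFP 24 h replicate 3, and that for controls was 797 with only the groups compared.

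Of 11 interferon genes tested, 8 fell in controls (median -3.22, camera adjusted p = 1.31e-08) and 6 in Fezf2GFP (median -2.85, adjusted p = 2.12e-08), with 8 lower in each adjusted over the list alone. With an estimated correlation the call was lost (adjusted p = 0.0773 and 0.0843). Cell division genes had a median of -1.58 in controls (adjusted p = 1.03e-18), where 22 of 26 fell, and of -1.55 in Fezf2GFP (adjusted p = 6.42e-20), where 20 fell (25 in each adjusted over the list alone). This call was lost too (0.0773 and 0.0843 with an estimated correlation). Of 15 intermediate progenitor genes 9 fell in controls and 7 in Fezf2GFP (9 in each adjusted over the list alone, with 1 higher in Fezf2GFP). Of 20 radial glia genes 9 and 3 fell (12 and 10 adjusted over the list alone), and of 14 Notch pathway genes 5 and 4 (9 and 5 adjusted over the list alone). Of 18 immature neuron genes, 8 rose in controls and 7 in Fezf2GFP (9 in each adjusted over the list alone). Camera called these lists in both comparisons. Each call was lost with an estimated correlation, where adjusted p = 0.0773 and 0.0843 for intermediate progenitors, 0.109 and 0.243 for radial glia, 0.105 and 0.244 for Notch and 0.105 and 0.172 for immature neurons.

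**Figure D5:**
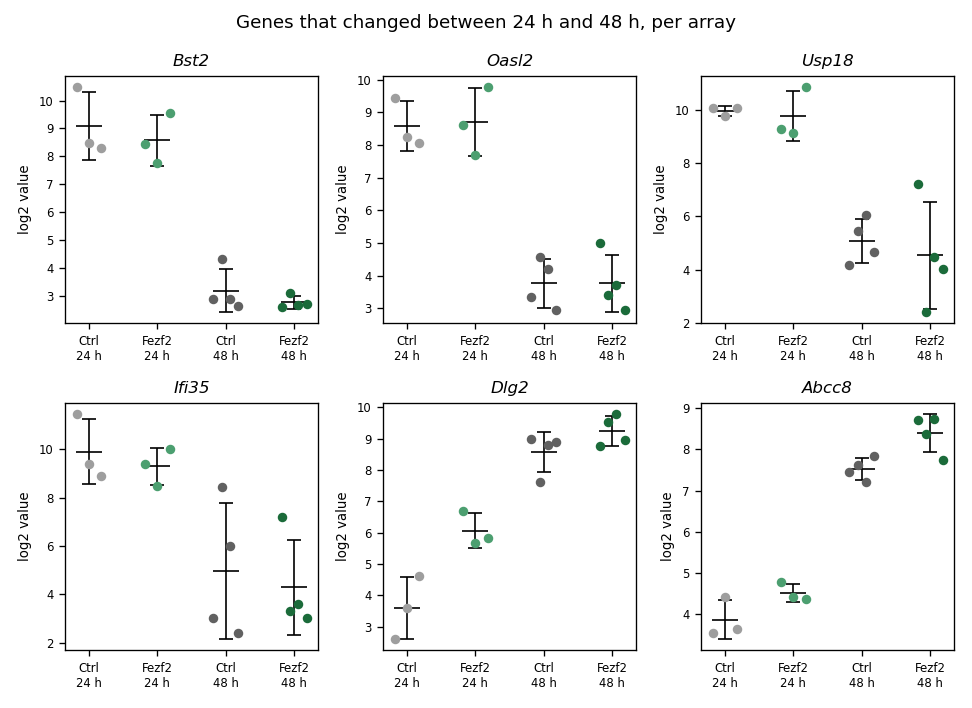
Log2 value (vertical axis) of 6 genes on each of the 14 arrays (points), by labelled vector and time, with the group mean and SD (bars; n = 3 at 24 h and 4 at 48 h). Bst2, Oasl2, Usp18 and Ifi35 have lower means at 48 h with each vector, Bst2 at 3.18 in controls against 9.09 at 24 h, while Dlg2 and Abcc8 have higher ones.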

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

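The tests on other splits of the arrays and on single arrays at 24 h were set before their results were seen; the tests on gene span, on the 2 control arrays that stood apart, on exchanged labels, on the Fezf2 probe set and on microglia markers, and the repeats of the splits without 1 array, were chosen only after the results were seen.

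Fezf2 was lower in the arrays labelled Fezf2GFP at 24 h. A trend with gene span is argued against as the whole cause, since with the trend removed the fall was -1.82 with an adjusted p of 0.0364. Exchanged vector labels stay open. The list chosen to decide, that of corticospinal genes, had a camera adjusted p of 0.488 with an estimated correlation at 24 h. That setting called 0 lists in each of the 5 comparisons, so it could not decide. With the preset correlation the list was upward (camera adjusted p = 0.0589 at 24 h and 0.020 at 48 h), but the 48 h call was lost with an estimated correlation (0.527). A probe set outside the part of the transcript that the vector carries may also account for it and stays open, since Fezf2 had only 1 probe set. Under that explanation the fall would be of the cells' own Fezf2 transcript, a hypothesis that no value here tests.

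More genes were higher than lower in the arrays labelled Fezf2GFP, 76.1% of those called at 24 h and 86.3% at 48 h, against 56.4% and 57.3% of all genes tested. With the trend with gene span removed the shares were 68.4% (91 higher, 42 lower) and 70.04% (180 and 77), and leaving out any 1 array they stayed at or above 63.6% (without CtrlGFP 24 h replicate 1) and 69.3% (without CtrlGFP 48 h replicate 4). Without the 2 control arrays that stood apart they were 62.0% (57 higher, 35 lower) and 82.5% (297 and 63), with lowest values of 60.0% (without CtrlGFP 24 h replicate 2) and 62.5% (without Fezf2GFP 48 h replicate 4). The 60.0% is of 15 genes and rests on 1 control array, assumed to vary like the other groups, so the 2 arrays stay open as the whole cause at 24 h. The rule of these tests asked only for more higher than lower genes among those called, which the other values met. The trend alone at 48 h is argued against as the whole cause (69.3% at lowest, against 57.3% of all genes). The lows of 63.6% at 24 h and, without the 2 arrays, 62.5% at 48 h are not far above the 56.4% and 57.3% of all genes. These gaps were not tested, so the trend alone at 24 h and the 2 arrays alone at 48 h stay open. The 2 arrays also had the most negative trends with gene span (rho = -0.272 and -0.266 across genes). Trend and arrays were not removed together, so their combination stays open. The vector itself, as a biological cause, stays among the open explanations too.

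Interferon genes fell from 24 h to 48 h with both vectors, 6 of 11 in both. Microglia or macrophages among the sorted cells are argued against as the source, since only 3 of 17 markers lay above the dim level at 24 h: Laptm5 at 6.75, Ctss at 6.50 and C1qb at 5.02. Their changes between times in controls were 1.34, 0.88 and 0.03, none of which passed, and the GFP gate would remove cells of this kind that carried no vector. A single array is argued against as well, since at least 5 genes were still called with both vectors without any 1 array at 24 h. A response to the electroporation or the DNA could be biological, and remains untested because no sample without electroporation was analysed here.

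Of the splits of the 6 arrays at 24 h only the real one, 1 of 10, gave as many genes (109, against 4 at most in the others) or as many lists (7 against 6), but 10 splits are too few for a share under 0.05. At 48 h chance is argued against for the count of genes: 1 of 35 splits, the real one, gave as many (322 against 54 at most in the others). The same held without any 1 of the 8 arrays. A share of 1 of 35 is the smallest these splits can give, and they treat the arrays as independent, which the labels do not state. For the lists chance cannot be excluded: 1 of 35 splits gave as many (8 against 7), but leaving out 1 array, 2 to 22 of 35 did. With an estimated correlation 0 of these lists were called, and leaving out 1 array gave as few as 2 (without CtrlGFP 48 h replicate 3 or Fezf2GFP 48 h replicate 3). Chance is also argued against, with the same limits, for the changes between times, with 1 of 35 splits each (1294 against 636 in controls, 1241 against 528 in Fezf2GFP). That test was not repeated without single arrays. For the 10 genes whose effect differed between times chance cannot be excluded, since 5 of 100 regroupings gave as many, the highest 32. Nor can it for the correlation of the effects at the 2 times: 3 of 100 regroupings gave 0.54 or more, the highest of the others 0.63, but 10 gave as much as the 0.34 without CtrlGFP 48 h replicate 2 and 12 as much as the 0.44 without Fezf2GFP 48 h replicate 4.

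The effect of the vector at 48 h minus that at 24 h differed from 0 by the test of the interaction for Hmgcll1 (1.95), Pappa2 (1.88) and Col9a1 (-2.73), with all group means above the dim level. It also did so for Cpxm2 (fitted value -3.02), with 1 group below that level on every array. Hmgcll1 and Pappa2 lay near the dim level in all groups but Fezf2GFP at 48 h. Tmem117, Stac2, Cdhr1 and Trim5 had fitted values of 3.36, 2.49, 2.12 and -1.57, but 3 of their 4 groups lay below the dim level on every array, so these are not measured sizes.

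In 25 of 242 groups of 4 arrays, 1 array was flagged by Dixon's ratio of its gap to the range, against 12.1 by chance at 1 in 20. The ratio does not measure distance, and some gaps were small, as for Rsad2 (4.76, others 4.88 to 4.90). The groups reuse the same arrays for named genes, so 12.1 is only a rough guide. CtrlGFP 48 h replicate 2 was flagged in its median (3.45, others 3.28 to 3.29) and for 7 genes. It was high for Aqp4 (3.18), Bst2 (4.31), Epb42 (4.46), Hpgd (3.36) and Tmem117 (2.95), and low for Dlg2 (7.62, others 8.79 to 8.99) and Pdzrn3 (12.12, others 13.14 to 13.25). Its values of Aqp4, Hpgd and Tmem117 lay below the dim level. CtrlGFP 48 h replicate 1 was high for Ephb1 (10.10, others 9.10 to 9.17), Wls (4.21) and Inhba (5.65). CtrlGFP 48 h replicate 4 was high for Draxin (10.82) and low for Mbp (6.08) and Nkd1 (5.62). Fezf2GFP 48 h replicate 1 was high for Inhba (7.92) and Ifi35 (7.21, others 3.03 to 3.62). Fezf2GFP 48 h replicate 2 was low for Btbd17 (5.64) and Rgs8 (9.82) and high for Cdhr1 (5.84), and replicate 3 was high for Gad1 (9.55). Fezf2GFP 48 h replicate 4 was high for Cpxm2 (5.10), Gucy1a1 (9.93), Neurod1 (13.96) and Wls (7.26, others 4.05 to 4.51) and low for Rsad2 (4.76).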

How the results depend on the processing

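Leaving out the 2 control arrays or 3 arrays that stood apart and removing the trend with gene span were chosen only after the data were seen. Of 3991 values of named genes under the alternatives, 3618 kept their sign and side of the threshold, 293 no longer passed, 61 newly passed and 19 reversed. Array weights gave 2030 genes at 24 h, 550 at 48 h, 240 for the difference, and 3077 and 3133 between times in controls and Fezf2GFP; the fit of the weights stopped before convergence, with a weight of 8.56 on CtrlGFP 24 h replicate 2. Only the groups compared, a fit of fewer arrays, gave 63, 168 and, between times in controls, 797. The difference gave 4 genes at a dim level of 6 and 4 without 3 arrays that stood apart. With an estimated correlation 0 lists were called at 24 h and 0 at 48 h, by fry 4 and 5, and 3 at 48 h with the span trend removed. The correlation of effects was 0.41 without the 2 control arrays. Leaving out each array in turn gave 50 to 165 genes at 24 h, 188 to 373 at 48 h, 0 to 12 for the difference, 911 to 1446 and 643 to 1433 between times, 3 to 9 and 2 to 8 lists, and correlations of 0.34 to 0.60. Reversed values, none of which passed, were those of Rsad2 at 24 h (0.080 with the mean of probe sets, 0.077 with array weights, 0.21 without 2 or 3 arrays, and -0.44 to 0.21 leaving out each array), Bst2 at 24 h (0.18 without 2 or 3 arrays; -0.999 to 0.18), Bst2 at 48 h (0.026 with array weights, 0.024 without 3 arrays), Pax6 at 24 h (-0.066 without 2 or 3 arrays; -0.066 to 0.45), Pax6 at 48 h (-0.26 with array weights, -0.29 without 2 and -0.11 without 3 arrays; -0.29 to 0.40) and Ephb1 at 24 h (-0.019 to 0.81). Apart from the fits with fewer arrays or genes, the cause was not tested. Signal over background limits the genes near the dim level.

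Whether replicate numbers pair the arrays is not settled. Of 7 pairs 4 had a correlation of deviations above 0.1, and 4 of the 7 control arrays correlated best with their own number. With the replicate number as a block, limma gave 81 genes at 24 h, 232 at 48 h, 0 for the difference (460 with an unadjusted p below 0.05), 1026 and 1055 between times, and 8 lists at each time.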

Other observations

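The tests of the lists between times were chosen only after the data were seen. Cajal-Retzius genes had only 4 tested members, too few for the list test, with a median log2 fold change of 1.34 at 24 h and 1.63 at 48 h in the arrays labelled Fezf2GFP. Besides Calb2, Reln, the secreted protein of these cells, stood at 1.59 (SE 0.72, limma adjusted p = 0.550) and 2.48 (SE 0.62, adjusted p = 0.0508), Cacna2d2 at 2.11 (SE 0.55, adjusted p = 0.108) and 0.78, and Ebf3 at 1.10 at 24 h, none of which passed; Reln, Cacna2d2 and Ebf3 were chosen after their values were seen. Adjusted over the list alone, 2 were higher at each time. Immature neuron genes had medians of 0.32 (camera adjusted p = 0.104) and 0.18 (0.731), with 0 of 18 passing at either time (2 and 0 higher adjusted over the list alone), and Stmn2 at 1.77 and Ina at 2.09 at 24 h. Radial glia had a median of 0.26 at 24 h (0.254) with 0 of 20 passing (1 lower adjusted over the list alone), Tnc at 1.45 and Hopx at -2.47. Notch pathway genes had medians of -0.06 (0.189) and 0.19 (0.485) with 0 of 14 passing at either time (0 higher and 2 lower, then 3 higher and 1 lower adjusted over the list alone), Jag1 at -1.32 at 24 h and Notch3 at 0.88 at 48 h. GABAergic and subpallial neurons at 48 h had a median of 0.54 (0.362) with 0 of 12 passing.

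Between the vectors, the lists of endothelium and pericytes, red blood cells, and oligodendrocytes and astrocytes did not pass camera. Endothelium and pericytes had medians of 0.19 (camera adjusted p = 0.911) and 1.00 (0.361), with Rgs5 at 1.15 (2 of 3 control arrays below the dim level) and 1.23, red blood cells -0.18 (0.314) and -0.15 (0.493), and oligodendrocyte and astrocyte genes 0.45 at 24 h (0.104). Microglia (3 members, medians 0.24 and 0.21), meninges (1 member, Ptgds, -0.89 and -0.20) and GABA synthesis (4 members, 0.65 and 0.72) were too small to test, and 0 members passed. Of the pathways, p53 response had medians of 0.36 (0.104) and 0.24 (0.227), the interferon response -0.17 (0.255) and -0.03 (0.429), FGF targets 0.41 (0.222) and 0.08 (0.883), and Wnt targets -0.08 (0.314) and, with a mean of 0.02, -0.13 (0.786). Immediate early and heat shock genes at 48 h had a median of 0.15 (0.412). Between times camera called 12 lists in controls and 10 in Fezf2GFP (0 in each with an estimated correlation), among them glutamate transmission, with medians of 0.67 in controls and 0.75 in Fezf2GFP (adjusted p = 0.206 and 0.243 with an estimated correlation). The oligodendrocyte and astrocyte list was also called between times with both vectors, upward, with medians of 0.24 and 0.69 (adjusted p = 0.0245 and 0.0264, and adjusted p = 0.279 and 0.244 with an estimated correlation), with 2 and 1 of 5 members passing (2 and 3 higher adjusted over the list alone).

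Some genes singled out after their values were seen differed between arrays of 1 group. Eif2s3y, a gene of the Y chromosome, lay at 4.26 on CtrlGFP 48 h replicate 2 and 3.76 on Fezf2GFP 24 h replicate 1, and between 9.80 and 11.63 on the other 12 arrays. Hbb-y, an embryonic globin, lay at 13.78 on CtrlGFP 24 h replicate 1 and 9.96 on Fezf2GFP 24 h replicate 3, and between 3.04 and 5.78 on the other 12.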
